A study of Mus musculus with 6 samples.

How the data were processed

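Total RNA from undifferentiated R1 mouse embryonic stem cells was hybridised to Mouse Genome 430 2.0 GeneChip arrays and scanned on a GeneChip Scanner 3000, per the labels' protocols, with 3 arrays for the mismatch control and 3 for the Pcl2 shRNA. The deposited values are an intensity per probe set, the MAS5 signal on a linear scale, computed by the authors with GCOS 1.4, per the labels and the submitters' processing notes. The values were positive, and the mean after trimming 2% from each end was 150.001 on all 6 arrays, so the authors' scaling was kept. Other settings of the signal algorithm are not given in the sources used here, and no detection calls were used. All 6 columns were assigned to samples by the labels.

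The table held 45101 probe sets. Of these 34945 named 1 gene, 932 several and 9160 none in the platform annotation, and 64 were control probe sets. Current symbols and chromosomes came from the reference gene table of GRCm38.p6, which held the genes of 34741 of the 34945. Because the sources name no genome build, that table served for names and chromosome membership and no coordinates are printed. Signals were transformed to log2(signal + 7), where 7 is the 20th percentile of all values, so that fold changes are on that scale and understate the changes of dim genes. A probe set was tested if it named 1 gene and its mean log2 value reached the 40th percentile (a signal of about 20.2). From 23185 such probe sets, the one with the highest mean represented each of 13094 genes. For 828 changed genes with more than 1 tested probe set, 93 had one of the other sign.

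Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), Pcl2 shRNA minus mismatch control, two-sided, with Benjamini-Hochberg adjusted p below 0.05. Gene lists and chromosomes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, over lists with at least 5 measured genes. A single value was tested by exact permutation over the 20 relabellings of 3 against 3 arrays. Figures were drawn from the same values.

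The groups, the tests, the alternatives, the 33 gene lists and the rule for named genes were set before the data were examined. The rule took Mtf2, the 12 largest rises and 12 largest falls past the threshold with non-overlapping groups, up to 4 members per list with the smallest p (or the 2 brightest where none passed), and Ezh2, Eed, Suz12, Jarid2, Pou5f1, Nanog, Sox2, Klf4, Tbx3, Foxd3 and Esrrb. It gave 121 genes. A further 29 were chosen after their values were seen, to complete counts of 5 or fewer, to give the leading members of 2 added lists and to single out members beside a count: Axin2, Bnip3, Ceacam1, Elavl3, Fut4, Gap43, Gata4, Gata6, Lama1, Mras, Nes, Notum, Pcgf5, Pim1, Rhox5 and Spry4 in the results, and Zyx, Cnn2, Tpm4, Tes, Tapbp, Erap1, Psmb10, Psme1, Actb, Acta2, Tpm2, Cd1d1 and Oasl2 in the closing section.

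Background was taken as 20.3, the highest signal on any array of the 27 bacterial control probe sets without a spike. A gene at or below it on all 3 arrays of a group has only a bound there, given as at least a fold against that level. This level was chosen after the data were examined, because the highest bacterial signal per array differed between the groups.

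The labels number the samples of each group 1 to 3 without saying that a number marks a shared culture or day. The deviations from the group means of samples with the same number correlated at 0.25 to 0.40, and those of samples with different numbers at -0.38 to -0.00, so the numbers were taken to pair the samples, on the data alone. Deviations cancel out within a group, so the first range being positive pushes the second below it. With 3 arrays per group few matchings are possible, so the numbers could match best by chance and the pairing is not established. The fit with the number as a block is given beside a result where it changes a call or moves a count by more than 1.5 times. Correlations of log2 values were 0.965 to 0.974 within groups and 0.943 to 0.962 between them, and no arrays were duplicates.

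Alternatives changed 1 choice at a time: quantile normalization, median centring, pseudocounts of 1 and 21, no signal filter or one at the 60th percentile, the mean of probe sets per gene, no cross-hybridising probe sets, eBayes without trend or robust, the replicate block, array weights, each array left out in turn and, chosen after the data were examined, a floor at the background level.

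The procedure was tested on simulated data made from the spread of these arrays. For the Pcl2 shRNA comparison, over 13101 genes, it recovered 36 of 99 genes changed by log2 1 and 90 of 100 changed by log2 2, and 7 of 133 calls were false. Far fewer genes were shifted in it than the 1651 called in the real data. The adjusted threshold depends on that share, so the recovery in the real data can differ. Of 34 simulated lists without a shift, 1 was called. Each probe set was simulated independently of the others. The simulation therefore does not test how list calls hold where the genes of a list are correlated. Probe sets naming no gene or several were left out of the comparisons.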

Results

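RNA from R1 mouse embryonic stem cells, a line kept undifferentiated in medium with leukaemia inhibitory factor (LIF), was measured on 6 expression arrays. In 3 samples the cells stably carried a short hairpin RNA (shRNA) against Pcl2, whose gene symbol is Mtf2, and in 3 samples they carried a mismatch control sequence. Pcl2 is a Polycomb-like protein that binds Polycomb repressive complex 2 (PRC2), the complex that methylates lysine 27 of histone H3, and the comparison asked which transcripts differ when Pcl2 is lowered. The labels call the 3 samples of each group biological replicates and say that the shRNA samples came from a single clone, so the p-values measure the spread between cultures, and the shRNA and the clone cannot be separated. Signals are given as mean ± SD with n = 3 arrays per group throughout, changes as log2 fold changes of Pcl2 shRNA over control with a standard error (SE), and p-values as limma's adjusted p unless named otherwise. The array number limits the precision.

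Mtf2 itself fell in the Pcl2 shRNA cells. Its brightest probe set gave a signal of 1723 ± 220 in the control and 1028 ± 150 in the shRNA cells, a log2 fold change of -0.74 (SE 0.17, adjusted p = 0.0157), which left 59.7% of the control level. A further 3 probe sets gave -0.68, -0.75 and -0.73, and in all 4 every shRNA array lay below every control array. The exact two-sided permutation p was 0.1 for each of them, the smallest that 3 against 3 arrays allow. The other 2 probe sets were dim and did not separate the groups: they gave 51.2 ± 10.8 against 61.7 ± 9.40 (exact permutation p = 0.3) and 14.5 ± 8.14 against 11.7 ± 3.40 (exact permutation p = 0.9). The Mtf2 call was lost without mismatch control replicate 1 (adjusted p = 0.0519) and without Pcl2 shRNA replicate 3 (adjusted p = 0.0574), while the value stayed at -0.75 and -0.63.

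Some core subunits of PRC2 were higher in the same cells. Eed rose from 1995 ± 450 to 3405 ± 400 (log2 0.79, SE 0.19, adjusted p = 0.0224), Suz12 by log2 0.72 (SE 0.17, adjusted p = 0.0196) and the methyltransferase Ezh2 by log2 0.52 (SE 0.15, adjusted p = 0.0433). Jarid2, which recruits the complex to its targets, rose by log2 0.85 (SE 0.20, adjusted p = 0.0207). Of the 13 PRC2 genes measured, these 4 rose, Mtf2 fell and 8 did not pass, with the same counts adjusted over the list alone. As a set they did not pass camera (adjusted p = 0.0668, and adjusted p = 0.374 with an estimated correlation), and did with the replicate block (adjusted p = 0.0393) and with the mean of probe sets (0.0463). They passed fry (fry adjusted p = 0.00442), which asks whether the genes of a list move on balance one way. Probe sets of Suz12 ranged from -0.22 to 0.93. Leaving out Pcl2 shRNA replicate 2 ended the calls of Suz12 (adjusted p = 0.0828), Jarid2 (0.092), Eed (0.101) and Ezh2 (0.178). Suz12 was also lost without control replicate 1 or shRNA replicate 3, Eed without control replicate 3 or shRNA replicate 1, and Ezh2 in each fit without 1 array except that without control replicate 3. With all arrays, Jarid2 was lost without cross-hybridising probe sets (0.0633), Eed without the eBayes trend (0.0509), and Ezh2 without a signal filter (0.0612) or without the trend (0.092).

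**Figure D1:**
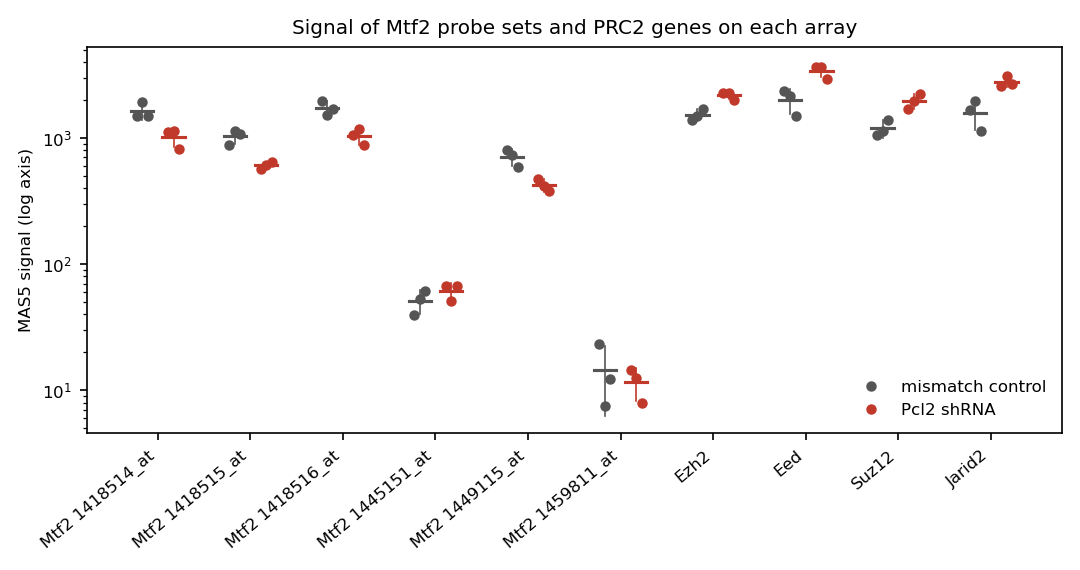
Signal on a log axis (MAS5 signal units) of the 6 Mtf2 probe sets and of Ezh2, Eed, Suz12 and Jarid2. Points are single arrays, horizontal lines group means and vertical lines 1 SD; for the brightest Mtf2 probe set the control arrays average 1723 and the Pcl2 shRNA arrays 1028.

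Across the 13094 genes tested, 1651 changed: 584 rose and 1067 fell. At least 2-fold changes were seen for 968 of them, 280 up and 688 down. The largest rises were those of Inhbb, a subunit of activin B, from 38.7 ± 17.2 to 461 ± 67.7 (log2 3.41, SE 0.26, adjusted p = 5.4e-05), of Khdc3, a maternal-effect gene of oocytes and early embryos (log2 3.15, SE 0.31), and of Mymx, which drives myoblast fusion (log2 3.02, SE 0.19). Another Inhbb probe set gave log2 1.46, and without any 1 shRNA replicate that one was the brighter and the value fell to as low as 1.42, still past the threshold. Next came the glutathione peroxidase Gpx2 (2.85), the myosin Myo1f (2.85), the cation exporter Slc47a1 (2.37), the transcription factor Tbx3 (2.37), the protease inhibitor A2m (2.36) and the lysosomal mannosidase Manba (2.21). Adgrd1, Hal and the meiotic cohesin gene Smc1b lay at or below background (20.3, the highest signal of the bacterial controls without a spike) in every control array and were at least 4.77-fold, 2.75-fold and 3.31-fold higher. Gpx2 and Myo1f had control means below that level with at least 1 array above it, and gave 2.91 and 2.87 with signals floored at it.

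The largest fall was that of Tagln, an actin-binding protein of smooth muscle, from 2376 ± 385 to 88.1 ± 85.5 (log2 -5.01, SE 0.48, adjusted p = 0.000185). The interferon-induced Gbp2b fell from 826 ± 343 to 27.1 ± 1.71 (log2 -4.53, SE 0.27). Krt8 and Krt18, keratins of simple epithelia, went from 3550 ± 1027 and 3247 ± 1260 to 147 ± 17.8 and 128 ± 20.9 (log2 -4.49, SE 0.22, and -4.51, SE 0.29). Gbp2 (-4.44) followed, with the growth factor binding protein Igfbp3 (-4.27), Anxa3 (-4.13), the matricellular protein Ccn1 (-4.12, another probe set -2.46) and Phldb2 (-3.93). Wnt4, the immunoproteasome subunit Psmb8 and Chst15 dropped to background in every shRNA array and by their brightest probe sets were at least 14.1-fold, 11.7-fold and 9.44-fold lower; another probe set gave log2 -1.49 for Wnt4 and -2.58 for Chst15.

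With the replicate number as a block, 3111 genes changed (1305 higher, 1806 lower), the 1651 among them. Without Pcl2 shRNA replicate 2 the count was 979, of which 261 were higher, and without Pcl2 shRNA replicate 1 it was 386 that were higher.

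Many genes that sustain pluripotency rose. Klf4 went from 986 ± 225 to 3350 ± 168 (log2 1.78, SE 0.18, adjusted p = 0.00025), Esrrb from 656 ± 83.4 to 1824 ± 226 (log2 1.47, SE 0.16) and Tbx3 from 115 ± 21.8 to 617 ± 29.9 (log2 2.37, SE 0.18), all transcription factors of the naive state. Tcl1, a cofactor of the kinase Akt, rose by log2 2.19 (SE 0.22) and Tfcp2l1 by log2 1.24 (SE 0.18). Sox2 rose by log2 0.76 (SE 0.18, adjusted p = 0.0186). Pou5f1 (log2 0.36, adjusted p = 0.334), Nanog (log2 0.59, adjusted p = 0.0889) and Foxd3 (log2 1.07, adjusted p = 0.16) did not pass, and with the replicate block Nanog (adjusted p = 0.0107) and Foxd3 (adjusted p = 0.0257) did. Foxd3 gave log2 0.42 without control replicate 3, and Pou5f1 0.18 without control replicate 3 and 0.22 without shRNA replicate 3. Of 39 measured pluripotency factors 21 rose, 1 fell and 17 did not pass; adjusted over the list alone, 27 rose and 1 fell. The exception was the fucosyltransferase gene Fut4, at background in the shRNA cells and at least 2.92-fold lower. camera gave an adjusted p = 3.6e-14 for the list, with a median log2 fold change of 0.85, and adjusted p = 0.306 with an estimated correlation. Sox2 was lost without control replicate 1 (adjusted p = 0.0519), shRNA replicate 2 (0.0662) or shRNA replicate 3 (0.0616), and Nanog passed without control replicate 3 (0.0281) and with array weights (0.0355).

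Some targets of LIF and Stat3, the signal that holds these cells undifferentiated, also rose. The receptor gene Lifr rose by log2 1.29 (SE 0.24, adjusted p = 0.00597), beside Klf4 and Tfcp2l1 above, and Junb fell by 0.99 on the log2 scale (SE 0.21, adjusted p = 0.0136). Of 16 measured, 5 rose (Klf4, Lifr, Tfcp2l1, Mras and Ceacam1) and 2 fell (Junb and Pim1), and adjusted over the list alone 7 rose and 2 fell (8 and 2 with the replicate block). Other probe sets gave up to log2 2.79 for Ceacam1 and 2.06 for Mras. The list passed camera (adjusted p = 0.00252), and had adjusted p = 0.306 with an estimated correlation. Calls were lost without 1 array for Junb (shRNA replicate 1, adjusted p = 0.0517), Mras (shRNA replicate 2, 0.0856), Ceacam1 (each array but control replicate 2, up to 0.164) and Pim1 (control replicates 2 and 3 and shRNA replicates 1 and 2, up to 0.133). With all arrays Ceacam1 was lost without a signal filter (0.0716) or the eBayes trend (0.0617), and Pim1 under 4 settings (median centring, no filter, mean of probe sets and no trend, up to 0.0791).

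**Figure D2:**
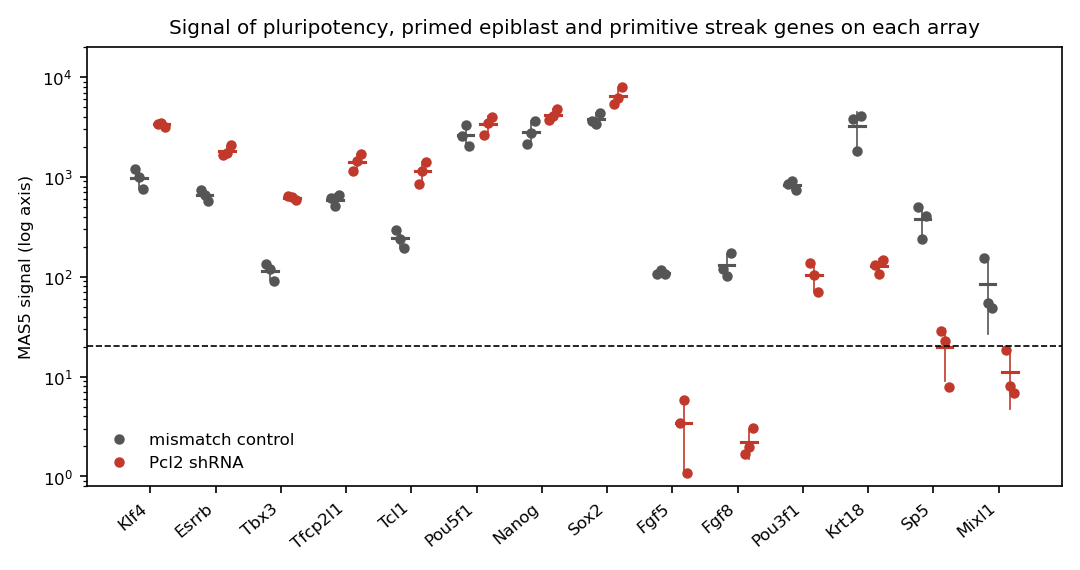
Signal on a log axis (MAS5 signal units) of 14 genes. Points are single arrays, horizontal lines group means, vertical lines 1 SD and the dashed line the background level of 20.3. Klf4, Esrrb, Tbx3, Tfcp2l1 and Tcl1 lie higher on every Pcl2 shRNA array, and Fgf5, Fgf8, Pou3f1, Krt18, Sp5 and Mixl1 lower.

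Many markers of the primed epiblast, the state that follows naive pluripotency, fell. Pou3f1 dropped from 832 ± 95.3 to 104 ± 33.9 (log2 -2.96, SE 0.23, adjusted p = 6.08e-05). The growth factor genes Fgf8 and Fgf5 dropped from 131 ± 36.4 and 110 ± 6.27 to background, at least 6.32-fold and 5.40-fold lower. Of 23 measured, 13 fell, 1 rose (Tdgf1, log2 0.89) and 9 did not pass; adjusted over the list alone, 15 fell and 2 rose, and with the replicate block 15 and 3. camera gave adjusted p = 7.52e-07, a median of -0.83, and adjusted p = 0.306 with an estimated correlation. The de novo DNA methyltransferase Dnmt3b fell by 0.81 on the log2 scale (SE 0.21, adjusted p = 0.0336). Dnmt3b lost its call in every fit without 1 array except that without control replicate 3 (up to adjusted p = 0.103), and also under median centring (0.0716), without a signal filter (0.0616) and without the eBayes trend (0.0659).

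Some primitive streak genes fell too. Sp5, a Wnt-induced transcription factor, went from 383 ± 134 to 19.6 ± 10.7 (log2 -3.90, SE 0.36, adjusted p = 0.000152), and Amot from 427 ± 132 to 46.2 ± 8.36 (log2 -2.99, SE 0.26). Mixl1 and Cdx2 reached background in the shRNA cells, at least 3.64-fold and 3.67-fold lower. Without control replicate 1 these bounds were 2.53-fold and 2.63-fold, and without control replicate 2 they were 4.3-fold and 5.85-fold. Of 17 measured, 5 fell (Amot, Cdx2, Fgf8, Mixl1 and Sp5), none rose and 12 did not pass, the same as adjusted over the list alone; the list had adjusted p = 0.000878 (median -0.34) and adjusted p = 0.374 with an estimated correlation. Another probe set of Amot gave 0.08.

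Trophectoderm markers fell in 6 of 23 cases: Krt8, Krt18, Krt19 (558 ± 239 to 42.3 ± 16.5, log2 -3.47, SE 0.36), Cdx2 and others, with Esrrb the 1 that rose. Adjusted over the list alone 7 fell and 3 rose, as with the replicate block. The list had adjusted p = 0.00834, and adjusted p = 0.527 with an estimated correlation; without control replicate 1 it did not pass (0.0991). Some markers on the endoderm list are expressed by fibroblasts too, and 7 of its 22 measured genes fell. Among them were the collagen chaperone Serpinh1 (1367 ± 666 to 226 ± 39.1, log2 -2.45, SE 0.31), Dab2 (log2 -1.79), Sparc (log2 -1.35, another probe set 0.30) and Cited1, at background and at least 5.92-fold lower (3.43-fold without control replicate 3 and 9.29-fold without control replicate 2). Lama1 rose, and the endoderm factors Gata4 (44.9 ± 2.42 and 45.2 ± 6.17) and Gata6 (41.1 ± 10.7 and 41.4 ± 3.53) did not pass. Adjusted over the list alone 7 fell and 2 rose, as with the replicate block, and the list did not pass (adjusted p = 0.0577; median -0.02, mean -0.44). It passed under 6 alternatives, 2 of them without 1 array: control replicate 2 (0.0234) or shRNA replicate 1 (0.031).

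Neural genes moved both ways. Sox11 dropped from 688 ± 118 to 168 ± 16.6 (log2 -1.98, SE 0.18), the neurofilament Nefl fell by 1.90 on the log2 scale, and Nefm reached background, at least 5.31-fold lower, while the tau gene Mapt rose by log2 1.48 (SE 0.20). In all 5 of 19 fell (Sox11, Nefl, Nefm, Nes and Gap43) and 2 rose (Mapt and Elavl3; other probe sets gave -0.90 for Sox11, 0.45 for Mapt and -3.47 for Nes), and 7 and 3 adjusted over the list alone, without passing camera (adjusted p = 0.256); the median was 0.01, the mean -0.32 and the test's direction down. Elavl3 lost its call in each fit without 1 array but that without shRNA replicate 1 (up to adjusted p = 0.198), without a signal filter (0.0845) and with the mean of probe sets (0.121), and Nes (0.0682) and Gap43 (0.0559) without control replicate 1; without any 1 shRNA replicate the other Nes probe set was the brighter and gave -3.88 to -3.22. Among 19 mesoderm and cardiovascular genes Pecam1 rose (log2 1.72, SE 0.28) and Actc1 (log2 -1.89, SE 0.36) and Foxc1, at least 2.07-fold lower, fell, as adjusted over the list alone, with 1 higher and 4 lower with the replicate block (adjusted p = 0.562 for the list).

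Targets of PRC2 in embryonic stem cells were examined as a list of developmental transcription factors. It was written from general knowledge, without binding data from these cells. Of its 82 genes 32 passed the signal filter and were tested in the main fit. Of 32 measured, Pou4f1, a factor of sensory neurons, rose by log2 1.01 (SE 0.23, adjusted p = 0.0181), Cdx2 and Foxc1 fell and 29 did not pass, the same as adjusted over the list alone, against 2 higher and 4 lower with the replicate block. The list did not pass camera (adjusted p = 0.256). Without a signal filter, where dimmer genes of the list entered, it did not pass either. Of the 39 Hox genes 9 passed the signal filter, and none of them changed, over all genes or adjusted over the list alone. The Hox list did not pass camera (adjusted p = 0.723, median -0.0040, mean 0.07, direction up), nor did it without a signal filter (0.993). Hoxa9 gave 115 ± 3.79 and 111 ± 26.7 and Hoxa5 102 ± 36.6 and 105 ± 24.6. Pou4f1 lost its call without control replicate 3 (adjusted p = 0.0513), shRNA replicate 1 (0.0653) or shRNA replicate 2 (0.0828).

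Among other chromatin genes, the demethylation enzymes Tet1 and Tet2 rose, Tet1 from 774 ± 215 to 1902 ± 252 (log2 1.32, SE 0.21, adjusted p = 0.0026) and Tet2 by log2 1.28 (SE 0.19), as did Zfp57, which guards imprints (log2 0.78). With Dnmt3b lower, 3 of 12 DNA methylation genes rose and 1 fell, 5 and 1 adjusted over the list alone and 6 and 1 with the replicate block. The list passed (adjusted p = 0.0202; adjusted p = 0.527 with an estimated correlation), but not without control replicate 3 (0.0982) or shRNA replicate 2 (0.0616); Zfp57 was lost without control replicate 1 (0.0693) or shRNA replicate 2 (0.114). Of 21 PRC1 genes, Yaf2 (log2 -1.49, SE 0.18), Phc2 (log2 -1.38, SE 0.18), E2f6 (log2 -0.87) and Pcgf5 (474 ± 203 to 223 ± 43.8) fell and Mga rose (log2 1.05), as adjusted over the list alone, with adjusted p = 0.231 for the list and 5 lower and 3 higher with the replicate block. E2f6 was lost without control replicate 1 (0.0692) or shRNA replicate 3 (0.0612), Mga without shRNA replicate 2 (0.0531) and Pcgf5 without each array but control replicate 1 (up to 0.139) and under 5 settings with all arrays (quantile normalization, no filter, mean of probe sets, no eBayes trend and array weights, up to 0.187). The Trithorax genes Kmt2c (log2 1.41, SE 0.22) and Rbbp5 (log2 0.94, SE 0.16) rose, 2 of 15, or 3 higher and 1 lower adjusted over the list alone and 4 and 2 with the block (adjusted p = 0.256 for the list). Small RNA genes gave 0 of 13 by limma, also adjusted over the list alone, and 1 higher and 1 lower with the block; Drosha gave 908 ± 319 and 904 ± 349 and Ago2 837 ± 159 and 700.5 ± 71.1 (adjusted p = 0.668 for the list).

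Several targets of FGF and ERK signalling fell. The phosphatase genes Dusp5 and Dusp4 went from 322 ± 50.1 and 554 ± 348 to 33.4 ± 8.74 and 88.1 ± 54.5 (log2 -3.04, SE 0.22, and -2.54, SE 0.44), and Phlda1 and Ier3 fell by 2.53 and 1.26 on the log2 scale. Of 17 measured, 7 fell, 1 rose (Spry4) and 9 did not pass, and 8 fell and 1 rose adjusted over the list alone, 10 and 2 with the replicate block (adjusted p = 0.00847 for the list, and adjusted p = 0.374 with an estimated correlation). Wnt targets fell for 5 of 14 genes, Sp5, Amotl2 (1714 ± 623 to 317 ± 58.9, log2 -2.37, SE 0.24), Cdx2, Wnt8a (log2 -1.66) and Axin2, and Notum rose; adjusted over the list alone 6 fell and 1 rose, and with the replicate block 8 and 2. This list passed (adjusted p = 0.0134; adjusted p = 0.475 with an estimated correlation), but not without control replicate 1 (0.0983) or with the stricter signal filter (0.199). Spry4 was lost without shRNA replicate 1 (0.051), Notum without shRNA replicate 2 (0.0502) and Axin2 in each fit without 1 array but that without control replicate 2 (up to 0.121), with quantile normalization (0.0508) and with the mean of probe sets (0.0653).

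The BMP target genes Id1, Id2 and Id3, which inhibit differentiation factors, fell by 1.70 (SE 0.31), 2.53 (SE 0.51) and 1.27 (SE 0.30) on the log2 scale. Another probe set of Id2 gave -0.37. They were the 3 of 13 BMP targets that passed, against 3 lower and 2 higher adjusted over the list alone and 4 and 2 with the replicate block, and the list did not pass (adjusted p = 0.267). Id3 was lost without control replicate 1 (adjusted p = 0.0668). Of 11 Nodal and Activin targets the co-receptor Tdgf1 rose, from 2635 ± 753 to 4757 ± 171, and Foxh1 fell (log2 -1.01), with 1 higher and 4 lower adjusted over the list alone, 1 and 3 with the replicate block, and adjusted p = 0.341 for the list. Foxh1 was lost without shRNA replicate 1 (0.0566).

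Several imprinted genes fell, and none rose. Igf2, a fetal growth factor, dropped from 632 ± 298 to 39.9 ± 15.4 (log2 -3.69, SE 0.39, adjusted p = 0.000324), Plagl1 from 785 ± 436 to 143 ± 10.8 (log2 -2.26, SE 0.32) and Peg10 from 669 ± 281 to 133 ± 23.4 (log2 -2.21, SE 0.27). Of 25 measured, 10 fell and 15 did not pass, and 11 fell adjusted over the list alone; adjusted p was 4.12e-05 for the list, and adjusted p = 0.222 with an estimated correlation. Gnas was lower by its brightest probe set (log2 -0.95), which can cross-hybridise, and another gave 0.35, so that its call was lost with the mean of probe sets (adjusted p = 0.308) and without cross-hybridising probe sets (0.455).

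Several germline genes rose: Dazl, an RNA-binding protein of germ cells, rose by log2 1.81 (SE 0.28, adjusted p = 0.0024), Stra8, needed for meiosis, rose by log2 1.46 (SE 0.24) and Kit by log2 1.33 (SE 0.24). Of 20 measured, 7 rose and 2 fell (Tdrkh, log2 -1.26, and Rhox5, log2 -1.66), and 8 and 2 adjusted over the list alone; adjusted p was 0.012 for the list, and adjusted p = 0.374 with an estimated correlation. Rhox5 was lost without control replicates 1 or 2 or shRNA replicates 1 or 2 (up to adjusted p = 0.124), without a signal filter (0.0692) and without the eBayes trend (0.0609), and gave log2 -1.09 without control replicate 1. Of 6 genes of the 2-cell-like state Tbx3 alone passed, also adjusted over the list alone, and 2 were higher with the replicate block (adjusted p = 0.0878 for the list).

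Several genes of the cell surface and matrix fell. The integrin Itgb1 went from 1141 ± 159 to a mean of 497 (log2 -1.18, SE 0.16, adjusted p = 0.00107), the surface glycoprotein Cd24a fell by 1.31 (SE 0.17) and the tight junction gene Cldn7 fell by 2.17 (SE 0.30) on the log2 scale, while Icam1 rose by log2 1.02. Of 22 measured, 8 fell and 1 rose, 11 and 1 adjusted over the list alone and 14 and 1 with the replicate block; adjusted p was 0.00082, and adjusted p = 0.231 with an estimated correlation. Genes typical of feeder fibroblasts, included because such cells can be present in stem cell cultures, fell for 6 of 22, also 6 adjusted over the list alone and 11 with the block. They include Tagln, Cald1 (2248 ± 1001 to 267 ± 35.8, log2 -2.95, SE 0.29, another probe set -0.38), Thbs1 (log2 -3.39) and Twist2 (log2 -1.79). The first pair bind actin, and Thbs1 is a matrix glycoprotein. This list had adjusted p = 0.000718, and adjusted p = 0.516 with an estimated correlation.

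Interferon response genes fell for 8 of 23, and 10 adjusted over the list alone. Besides Gbp2 and Psmb8, these were led by B2m, the light chain of class I histocompatibility molecules (1183 ± 271 to 161 ± 34.1, log2 -2.82, SE 0.21, adjusted p = 5e-05), and Gbp3, at background in the shRNA cells and at least 6.82-fold lower. None rose, against 1 with the replicate block. The list had adjusted p = 0.000327, and adjusted p = 0.467 with an estimated correlation.

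Of 24 G1/S genes Ung (log2 0.59), Mcm3 (log2 0.62) and Mcm5 (log2 0.53) rose, also adjusted over the list alone, with 7 higher and 1 lower with the replicate block; adjusted p was 0.00224, and adjusted p = 0.374 with an estimated correlation. Of 21 G2/M genes Hmmr rose (log2 0.59), none adjusted over the list alone and 5 with the block, and the list did not pass (adjusted p = 0.0577) but did with the block (0.0475) and under 5 other alternatives, among them leaving out control replicate 2 (0.0333) or 3 (0.00844). Each of these 4 genes lost its call in 5 of the 6 fits without 1 array, up to adjusted p = 0.102 for Ung, 0.168 for Mcm3, 0.192 for Mcm5 and 0.157 for Hmmr. The fits that kept it were those without control replicate 2 for Ung, Mcm3 and Mcm5 and without control replicate 3 for Hmmr. With all arrays, calls were also lost under other settings: Mcm5 under 6 (up to 0.123), Hmmr under 5 (up to 0.0941), Mcm3 under 4 (up to 0.0854) and Ung without the eBayes trend (0.0648).

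The p53 targets Perp (758 ± 295 to 204 ± 60.1, log2 -1.80, SE 0.31), Plk2 (log2 -1.55) and Phlda3 (log2 -0.85) fell, 3 of 22 and also 3 adjusted over the list alone, with 9 lower and 1 higher with the block. The list had adjusted p = 0.0391, and adjusted p = 0.576 with an estimated correlation; it was lost without control replicate 3 (0.182) or shRNA replicate 2 (0.322), as was Phlda3 (0.0574 and 0.111), and with quantile normalization (0.0516). Of 23 glycolysis and hypoxia genes, the phosphofructokinase Pfkp (log2 1.66, SE 0.23), the oxygen sensor Egln3 (log2 1.23), Pdk1 (log2 0.74) and Bnip3 (log2 1.18) rose, and the glucose transporter Slc2a1 fell from 4199 ± 493 to 2097 ± 236, as adjusted over the list alone, with 8 higher and 2 lower with the block. That list had adjusted p = 0.0211, and adjusted p = 0.576 with an estimated correlation; it was lost with quantile normalization (0.133), with the mean of probe sets (0.0521) and without control replicate 1 (0.2) or shRNA replicate 3 (0.104). Pdk1 was lost without shRNA replicate 2 (0.0637), and Bnip3 without control replicates 1 or 3 or shRNA replicates 2 or 3 (up to 0.062).

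Of 19 cholesterol synthesis genes Sc5d fell (log2 -1.05, SE 0.20), the 1 that passed, also adjusted over the list alone, against 4 with the block; adjusted p was 0.0142, and adjusted p = 0.576 with an estimated correlation. The list was lost without control replicate 3 (0.278) and Sc5d with the mean of probe sets (0.134). Of 28 ribosomal protein genes Rps25 (log2 1.37, SE 0.20) and Rpl12 (log2 1.04) rose, 1 adjusted over the list alone; adjusted p was 0.0263, and adjusted p = 0.634 with an estimated correlation. It was lost with quantile normalization (0.484) and without control replicate 1 (0.475) or shRNA replicate 3 (0.348), and Rpl12 without any 1 shRNA replicate (up to 0.0988), without a signal filter (0.0647) and without the eBayes trend (0.0634); without control replicate 1 Rpl12 gave log2 0.66.

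Of 13 heat shock genes Cryab (268 ± 156 to 19.2 ± 12.8, log2 -3.27, SE 0.50), Hspa4l (log2 -1.11) and Hspa1a (log2 -1.34) fell, 4 adjusted over the list alone and 5 lower and 1 higher with the block, without the list passing (adjusted p = 0.309; median 0.03, mean -0.48, direction down). Hspa4l was lost without control replicate 3 (0.0571) or shRNA replicate 2 (0.081) and with the mean of probe sets (0.063), and Hspa1a under 9 alternatives, 3 of them without 1 array: control replicate 1 (0.116, log2 -0.87), shRNA replicate 2 (0.13) or shRNA replicate 3 (0.135). The endoplasmic reticulum stress genes Xbp1 (log2 0.80, SE 0.14) and Dnajb9 (log2 0.72) rose and Atf3 (log2 -1.72) fell, 3 of 24 and the same adjusted over the list alone, with 4 higher and 3 lower with the block (adjusted p = 0.26 for the list). That list passed without control replicate 2 (0.0199) or shRNA replicate 1 (0.031).

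**Figure D3:**
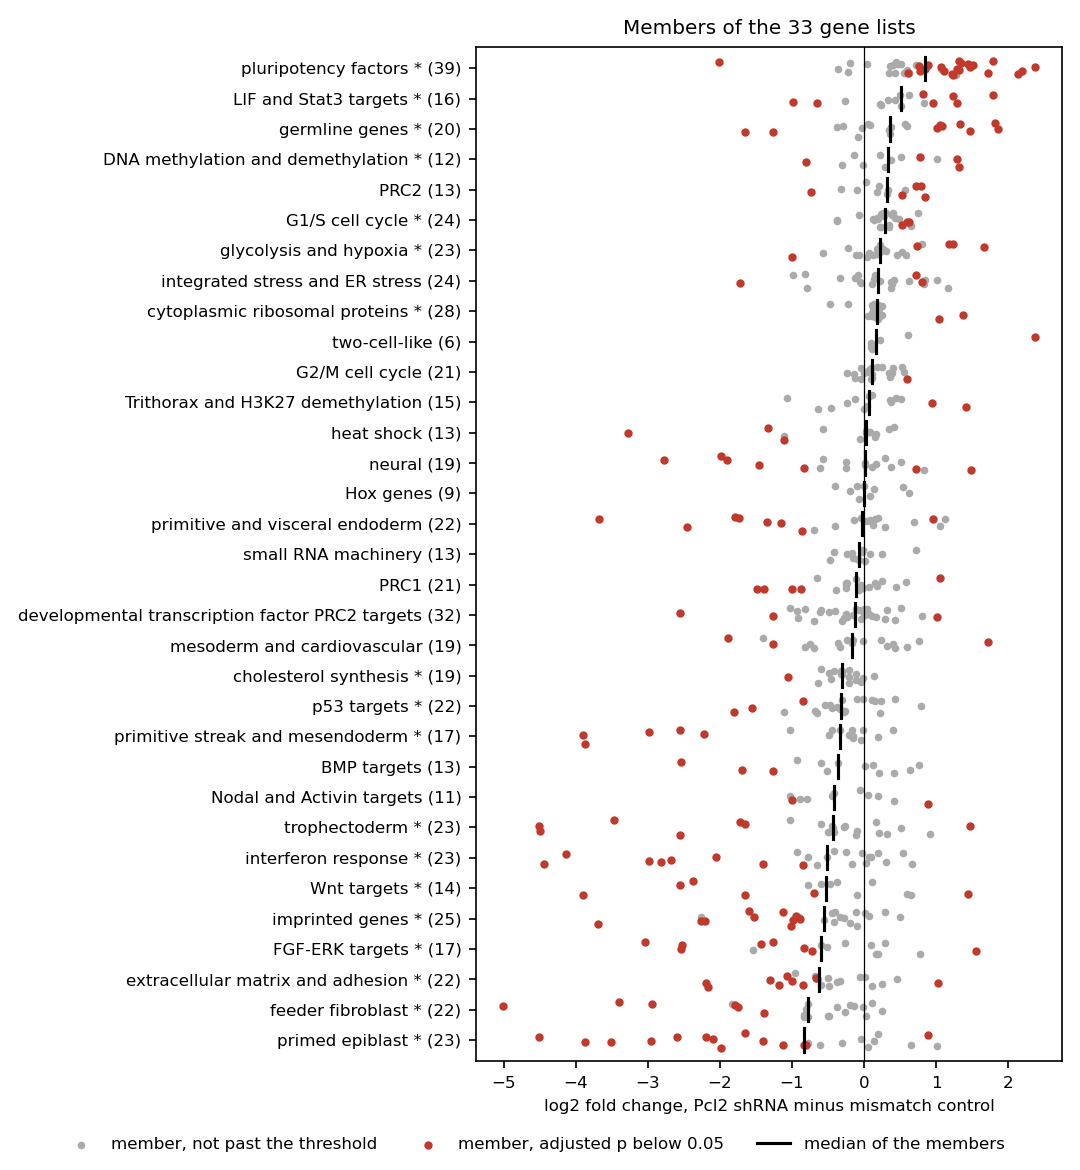
log2 fold change (Pcl2 shRNA minus mismatch control) of each measured member of the 33 gene lists, ordered by median. Points are genes (red, adjusted p below 0.05 over all genes), black bars are medians, the number of measured genes is in brackets and an asterisk marks the 18 lists past the camera threshold, with medians from -0.83 for the primed epiblast to 0.85 for the pluripotency factors.

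In all, 18 of the 33 lists passed camera at a preset correlation, 7 higher and 11 lower. With an estimated correlation none passed (lowest adjusted p = 0.222), and 5 had an unadjusted p below 0.05. By fry, which asks whether the genes of a list move on balance one way, 12 passed. Among them were PRC2 (fry adjusted p = 0.00442) and the 2-cell-like list (0.0116), which did not pass camera. The feeder fibroblast, trophectoderm, G1/S, DNA methylation, cholesterol, glycolysis, ribosomal protein and p53 lists passed camera but not fry (fry adjusted p 0.058 to 0.416). Some genes belong to several lists, so the results of the lists are not independent. Tet1, Tet2, Zfp57 and Pecam1 are also on the pluripotency list, and Dnmt3b is also on the primed epiblast list.

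RNA quality measures showed little difference between the groups. The log2 ratio of the 3 prime to the 5 prime control probe set was -0.30 ± 0.01 in control and -0.30 ± 0.02 in shRNA arrays for Gapdh and 0.25 ± 0.05 and 0.31 ± 0.09 for Actb, with exact permutation p of 0.7 and 0.5 (two-sided, smallest possible 0.1). The spiked BioB and Cre controls differed by log2 0.13 and 0.16 (exact p = 0.6 for both). The brightest of the 27 bacterial probe sets without a spike, used here to set the background level, was higher on the shRNA arrays, 19.4 ± 1.22 against 11.6 ± 0.47 (exact p = 0.1). Their median overlapped between the groups, 1.16 to 2.61 on the control arrays and 1.93 to 3.27 on the shRNA arrays. A raised background as a whole is therefore not shown. None of the 21 chromosomes passed camera, with 1 at an unadjusted p below 0.05; chromosome 6 had the lowest p (0.00674, adjusted p = 0.142), with a median log2 fold change of -0.11 over 624 genes. It passed with the stricter signal filter (adjusted p = 0.0435).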

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

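The test in this paragraph was chosen after the data were seen. Probe sets that name no gene or several genes were not part of the comparisons, and 3837 of them passed the signal filter. Tested in the same way on their own, 48 were higher and 57 lower in the Pcl2 shRNA cells than in the control. What they measure was not identified here.

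The tests of RNA quality and array scaling in this paragraph were chosen after the count was seen, and the splits before. Other splits of the 6 arrays into 3 and 3 gave no changed genes, against 1651 for the real one, which was the 1 of 10 splits with as many; the 3 other splits that part all pairs gave 0 with the replicate block as well, against 3111. With 10 splits a share under 0.05 cannot be reached. Each other split also mixes arrays of both groups on each side. A large difference between the groups then adds to the spread and lowers the count, whatever its source. A difference in RNA quality is argued against, because the log2 ratio of 3 prime to 5 prime signal differed by at most 0.0620 between the groups. Array scaling as the whole source is argued against as well, since the lower count under quantile normalization or median centring was 1655. The shRNA against its mismatch control is the biological difference that the design names, and it stays open beside the properties of the single clone.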

How the results depend on the processing

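Under the other settings the count of changed genes moved most with the replicate block, which gave 3111 (1305 higher, 1806 lower) and held all 1651, and array weights gave 885 higher. Leaving out 1 array gave 979 to 1598 changed genes (261 to 577 higher, 718 to 1021 lower) and 825 to 1048 changed at least 2-fold, with fewer samples; the other settings stayed within 1.5 times. Mtf2 ranged from -0.84 to -0.63 without 1 array and lost its call 2 times, without mismatch control replicate 1 and Pcl2 shRNA replicate 3. The 18 lists past camera fell to 0 with an estimated correlation and were 14 to 21 without 1 array. Of chromosomes, 0 passed and 1 did with the filter at the 60th percentile; without 1 array the count stayed at 0.

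Values that changed sign were all without a call except that of Gnas, 0.35 without cross-hybridising probe sets, where another probe set represents it. These were Ago2 (0.15, same setting), Hoxa9 (-0.19 to 0.13 without 1 array), Hoxa5 (-0.23 to 0.28 without 1 array), Drosha (0.0301 with median centring, 0.0432 with the mean of probe sets, -0.30 to 0.29 without 1 array), Actb (-0.0199 with quantile normalization, -0.0576 to 0.31 without 1 array), Gata4 and Gata6 (-0.0297 and -0.0064 with quantile normalization, -0.10 and -0.0579 with array weights, -0.0662 to 0.10 and -0.16 to 0.17 without 1 array), and the means of the Hox list (-0.0289 without a filter, -0.0041 with array weights, -0.0530 to 0.14 without 1 array, -0.0900 with the background floor), the stress list (-0.0289 to 0.36 without 1 array) and the small RNA list (0.0124 with median centring, 0.0011 with array weights). Their cause was not tested. Of 2794 values of named genes 2612 kept direction and side, 157 kept direction but lost the call, 4 gained it and 21 changed sign. Of 658 for lists the counts were 601, 34, 16 and 7. The block changed the calls of Nanog, Foxd3, PRC2 and G2/M and no other named call. Genes at or below background, 20.3, on all 3 arrays of a group have only bounds; Gpx2, Myo1f, Pou4f1, Wnt8a, Twist2, Sp5 and Cryab, with a group mean below it but 1 or more arrays above, kept direction and call with the background floor.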

Other observations

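The fall of Tagln and Cald1 extended to other genes of the actin cytoskeleton. Zyx, a focal adhesion protein, dropped from 797 ± 86.3 to 119 ± 20.4 (n = 3 per group, log2 -2.68, SE 0.18, limma adjusted p = 3.09e-05), Cnn2 from 2495 ± 283 to 463 ± 107 (log2 -2.43, SE 0.19), the tropomyosin Tpm4 from 2403 ± 344 to 665 ± 109 (log2 -1.84, SE 0.17) and Tes from 613 ± 173 to 148 ± 6.28 (log2 -1.96, SE 0.22). These belong to a list of targets of actin-SRF and YAP signalling written after the main result but before the values of its genes were looked at. Of its 24 measured genes 18 fell and none rose, with Actb, 7339 and 8034, among those that did not pass. Acta2 and Tpm2 of the fibroblast list, named below, lost their calls without Pcl2 shRNA replicate 2 (limma adjusted p = 0.0721 and 0.0699), and Acta2 without Pcl2 shRNA replicate 3 (0.0605).

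Further class I antigen presentation genes fell beside B2m and Psmb8. Tapbp, which loads peptides, dropped from 706 ± 137 to 158 ± 14.6 (log2 -2.10, SE 0.19, limma adjusted p = 0.000117), Erap1, which trims them, from 88.5 ± 15.5 to 22.6 ± 2.65 (log2 -1.68, SE 0.23), and the proteasome genes Psmb10 and Psme1 fell by 1.46 and 1.01 on the log2 scale. Of 13 measured genes of this list, written in the same way, 7 fell and Cd1d1 rose, a call lost without control replicate 3 and without each shRNA replicate (limma adjusted p up to 0.0906).

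The test of collagens below was chosen after the result was seen, and that of actin-SRF and YAP targets before. Fibroblasts in the control cultures stay open as the source of the fall of Tagln, Acta2, Cald1 and Tpm2. The collagens of the list lost 0.0232 of the signal that these genes lost (medians), but brightness is not comparable between probe sets and no fibroblast profile was at hand, so the ratio decides nothing; on the log2 scale 5 of the 6 collagens were lower (median -0.81, none past the threshold), and Thbs1 and Twist2 fell. A candidate explanation is lower activity of actin-SRF and YAP target genes. Their members not looked at before had a median log2 fold change of -1.53 (unadjusted camera p = 1.07e-17, and 0.0181 with an estimated correlation). On that unadjusted measure 5 of the 33 fixed lists also lay below 0.05, and none of them passed once adjusted. Fibroblasts express actin-SRF and YAP targets too, so the fall of these targets does not part the explanations.

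The test of type I genes was chosen after the result was seen, and that of antigen presentation before. The 11 type I members with a control signal above 60 had a median log2 fold change of 0.0731 (quartiles -0.34 and 0.25), with Oasl2 the 1 that fell. As a group these members gave no sign of a type I interferon response of the control cells to double-stranded RNA. The subset was tested after the fall was seen and holds 1 of the 8 interferon list genes that fell. Such a response is therefore not excluded. The antigen presentation list was lower, with a median of -1.01 (unadjusted camera p = 7.5e-06, and 0.00903 with an estimated correlation). A lower level of shared regulation stays a candidate for the fall of the interferon list, and no regulator was tested. The antigen presentation list was written after the main result was seen, so its fall widens the pattern and does not test that cause.

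An extra or lost chromosome in the clone was tested with bounds set before the result: a shift of 0.3 or more for it, and every chromosome within 0.15 against it. The largest difference from all other chromosomes was -0.14, for chromosome 6, which lies inside the 0.15 bound. The 95% interval over 1000 resamplings of genes, -0.18 to -0.09, was added after that value was seen. It crosses 0.15, so a shift past that bound stays open where the value alone would have ruled it out. It stays short of 0.3, the bound set for an extra or lost chromosome. Resampling genes leaves out the spread between arrays and treats genes as independent, so the interval may be too narrow to decide. With an estimated correlation camera gave chromosome 6 an adjusted p = 0.967. Among the other chromosomes with 100 or more tested genes the largest difference was 0.05, for chromosome 13. Chromosome Y, with 6 tested genes, is not covered.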
